A study of Homo sapiens with 2 samples.

How the data were processed

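Single-cell RNA was measured in 2 libraries of human pDC, 1 cultured with CpG-A ODN (5 µM, 5 h) and 1 control. Libraries were made with the 10x Chromium v2 kit and sequenced on a HiSeq 3000, per the labels. The deposited matrices hold whole-number UMI counts per gene and barcode, not normalized, for 33694 genes. The submitters' processing notes name Cell Ranger 2.2, Seurat 3 and the genome build GRCh38, with no role stated. Which filters had been applied to the barcodes, and whether counting used the strand, is not given in the sources used here. No barcode had fewer than 1854 UMIs. Whether interleukin-3 or GM-CSF, which the labels mention for some cultures, was present in these cultures is also not given in the sources used here. The group of each library came from its treatment label.

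Barcodes with at least 200 genes and at most 20% mitochondrial UMIs were kept, a filter that removed 0 barcodes. Each library was clustered on its own. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were scaled to a maximum of 10, and 30 principal components, 15 neighbours and Leiden clustering at resolution 1.0 followed (scanpy 1.11.5, igraph 0.11.9, anndata 0.12.19, scikit-learn 1.9.0, Python 3.11.15). Clusters were named from marker genes of 15 cell classes fixed before the data were examined, like the comparisons, the gene lists, the naming rule and most alternatives. A cluster was called pDC-like when the 19 pDC markers were detected on average in at least 50% of its cells and no other class had more markers than pDC among its 10 leading genes. Leading genes were ranked by CPM plus 20 against the mean of the other clusters of the library, among genes detected in at least 50% of the cluster's cells. This threshold and ranking were set after the clusters had been seen, and 3 rankings were tried. Clusters resting on under 3 detected markers stayed unnamed. Scrublet, run in each library with 20 principal components, called 1 doublet in the ODN library and 2 in the control library. These were kept, and leaving them out was an alternative. Y-linked genes, immunoglobulin and T cell receptor segments, and genes often set by a common donor variant were kept out of the named genes.

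UMIs of pDC-like cells were summed per library and given as CPM, UMIs scaled to the same total in each library. A gene was measured when both sums together held at least 30 UMIs, which left 9856 genes, of which 9816 entered the naming rule. The ratio of CPM was given with an exact conditional binomial 95% interval (scipy 1.17.1, numpy 2.4.6, pandas 2.3.3). Shares were given with exact Clopper-Pearson intervals and levels with exact Poisson intervals. No p-value, standard error or count of changed genes was made, since each group has 1 library and cells are not replicates. Against 0 counts, a ratio was computed at a floor of 3 counts over the group's sum. A measured gene with 0 UMIs in 1 sum holds at least 30 in the other. At this floor such a gene always counts as at least 2-fold higher or lower. Named were the 15 genes with the highest lower end of the interval, the 15 with the lowest upper end, the 3 most extreme members of each of 26 fixed gene lists, every measured amino acid transporter at 1.5-fold or more in either direction, and SLC7A5 and SLC3A2. Not every gene this rule picks is reported here. Each list was described by its measured members, those at least 2-fold higher or lower by size alone, its median log2 ratio, and the percentile of that median among 10000 random lists of the same size drawn from 20 bins of mean CPM. Such a percentile describes these libraries. Gene coordinates came from the GENCODE annotation of GRCh38, matched by Ensembl identifier.

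Interferon shares were taken after thinning each cell to 4000 UMIs, the depth near percentile 10 of pDC-like cells, with shallower cells left out. Within the ODN library, pDC-like cells were split at 3 interferon UMIs. Plots were drawn with matplotlib 3.10.9.

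The sums and intervals were tested on simulated data drawn from these libraries for the comparison of ODN with control pDC-like cells, in a step of 9866 genes. The interval held the true ratio for 95.9% of 9675 unchanged genes. For changed genes it held it for 88.0% at 1.5-fold, 93.9% at 2-fold, 97.9% at 4-fold and 100% at 8-fold. It lay off 1 in the right direction for 72.0% of 50 genes set to 1.5-fold, 95.9% of 49 set to 2-fold, and 100% of those set to 4-fold and 8-fold. Of 40 unchanged lists, 39 fell in the middle 95% of random lists, and a list raised 2-fold fell at percentile 100. The simulation holds counting error, with no spread between cells and no difference between cultures. Its counts were drawn from the Poisson model on which the interval rests, so coverage near 95% follows from the design.

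Alternatives were a median ratio size factor, CPM without response, ribosomal and mitochondrial genes in the total, the mean of per-cell CPM, all cells, minima of 10 and 100 UMIs, a strict cell filter (500 genes, 10% mitochondrial UMIs), thinned cells, doublets left out, 1 UMI added, other thinning depths and interferon thresholds, Leiden resolutions 0.5 and 2.0, and joint clustering of both libraries without the response lists. Added after seeing the data were the other rankings of leading genes, sums over the jointly clustered class, sums without the CX3CR1-led control cluster, sums without clusters led by stress genes, and sums without ODN cells holding at least 3 interferon UMIs. Sequencing reads were not used here.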

Results

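Plasmacytoid dendritic cells (pDC) are blood cells specialised in releasing type I interferon when they sense viral nucleic acid. Human pDC were purified from healthy donor buffy coats by negative selection, which takes other blood cells away with antibodies and leaves the pDC untouched. They were then kept in culture for 5 h without stimulus or with CpG-A ODN at 5 µM. CpG-A ODN (ODN2216) is a synthetic DNA oligonucleotide that activates the endosomal DNA sensor TLR9. Single-cell RNA libraries were made with the 10x Chromium system, which tags each captured messenger RNA with a molecular identifier (UMI). Each treatment had 1 library. The ODN library held 733 barcodes with 7039020 UMIs in all, with a median of 7276 UMIs per barcode (range 2729 to 40224). The control library held 736 barcodes with 5617716 UMIs and a median of 6920 (range 1854 to 48791). With 1 library per group there are no replicates and no replicate check. The ratios below compare these libraries, and every interval is an exact 95% interval that covers counting error only. Whether both libraries came from the same donors is not given in the sources used here.

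Most barcodes of both libraries expressed a broad set of pDC marker genes, such as the receptors CLEC4C and LILRA4 and the transcription factor TCF4. Clusters called pDC-like held 611 of 733 barcodes in the ODN library (83.4%, interval 80.5 to 86.0%). In the control library they held 439 of 736 (59.6%, 56.0 to 63.2%). A cycling class, led by the proliferation genes MKI67, TOP2A and TYMS, held 41 barcodes (5.59%) in the ODN library and 33 (4.48%) in the control library. No cluster could be named for any other cell class. Within the pDC-like class, ODN clusters 6, 3 and 4 were the largest, with 138, 118 and 100 cells, and control clusters 4 and 2 were the largest, with 131 and 129 cells. Stress and immune genes led several of these clusters. ODN cluster 3 was led by interferon genes, ODN cluster 1 by genes that included ATF3 and SQSTM1, and ODN cluster 2 by DNAJB1, HSPH1, FOS and JUN. Control cluster 3 was led by genes that included SQSTM1, PPP1R15A and ZFP36, and control cluster 6 by CX3CR1.

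Unnamed clusters held 81 barcodes (11.1%) of the ODN library and 264 (35.9%) of the control library. They included barcodes nearly free of both the nuclear RNA MALAT1 and mitochondrial UMIs (51 and 120 barcodes). Small clusters led by FSCN1, a marker of mature dendritic cells, held 14 ODN barcodes, where CCL22 and CCL17 also led, and 39 control barcodes, where CCR7 and LAMP3 also led. An ODN cluster of 16 barcodes was led by LYZ and CXCL10. A control cluster of 17 was led by ribosomal genes and was also nearly free of MALAT1 (162 CPM, 65.3 to 334), but had a median of 1.12% mitochondrial UMIs. A control cluster of 88 barcodes had 16 of the 19 pDC markers in at least 50% of its cells, but the cytotoxic granule gene NKG7 stood among its leading genes, which left it unnamed. NKG7 was at 231 CPM there. It was also at 147 CPM in control cluster 2, at 156 and 151 CPM in ODN clusters 5 and 8, and at 41.1 to 97.2 CPM in the other pDC-like clusters. Whether these 88 barcodes are pDC was not settled. The naming threshold and the ranking of leading genes were set after these clusters had been seen. Of the 3 rankings tried, the others gave a control pDC-like share of 51.0% and 71.6%, with no difference in the ODN share. Under the ranking that gave 51.0%, the ODN cycling class held 0 of 733 barcodes instead of 41, and the control class was the same. The shares of the 2 libraries are therefore not read against each other.

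The first comparison asks which genes differed between pDC-like cells with and without CpG-A ODN. The pDC-like cells of the 2 libraries were not alike overall. With both libraries clustered together and the response lists left out, the pDC-like clusters held 130 ODN and 0 control cells, 68 and 0, 174 and 15, 106 and 5, 9 and 185, and 24 and 210, with 83 and 46 in the most mixed. Interferon genes stood furthest apart. IFNB1 (ENSG00000171855, chromosome 9, 21077105 to 21077963, GRCh38), which encodes interferon beta, stood at 4646 CPM (UMIs scaled to the same total in each library) in the ODN library. The control library held 1 IFNB1 UMI, a ratio of 17417 with an interval from 3126 to 687973. IFNA2 was at least 4430-fold higher in the ODN library and IFNA8 at least 4020-fold higher, against a floor of 3 counts over the control sum. Their exact intervals begin lower, at 3602 and 3269. The chemokine genes CCL4 and CCL3, whose products draw in other immune cells, were 1085-fold (465 to 3343) and 833-fold (404 to 2073) higher. The log2 ratio of CCL3, 9.70 as reported, was 8.16 over all cells. It was 8.05 in ODN cells with fewer than 3 interferon UMIs, an alternative chosen after seeing the data. The sums of pDC-like cells rest on 5822727 UMIs in the ODN library and 3748527 in the control library. Over all measured genes the median log2 ratio was -0.15, and a size factor from the median ratio moved it to 0.00.

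All 16 measured type I interferon genes were at least 2-fold higher in the ODN library, with a median log2 ratio of 10.55 with genes at 0 in the control at their bound. This median was 8.91 with cells thinned to the same depth and 12.09 with 1 UMI added. The list lay at percentile 100 of 10000 random lists of the same size and expression level. Of the 15 genes that the naming rule picked as highest, 13 were type I interferons: IFNA2, IFNA8, IFNB1, IFNA1, IFNW1, IFNA10, IFNA16, IFNA21, IFNA17, IFNA4, IFNA5, IFNA6 and IFNA14. The other two were IFNL1 and CCL4. The alpha interferon genes are near-identical copies, so how the UMIs divide among them is uncertain. The type III interferons, which act mainly at epithelial surfaces, had all 3 measured members higher (median 8.16 at the bound, percentile 100). IFNL2 and IFNL3 had 0 control UMIs and so were placed at least 2-fold higher in the same way. IFNL1 stood at 1239 CPM against 1 control UMI, a ratio of 4645 (833 to 183486). Against the floor of 3 counts IFNL3 was at least 287-fold higher, with an exact interval that begins at 233.

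Interferon-stimulated genes, the antiviral genes switched on by interferon receptor signalling or directly by interferon regulatory factors, were higher as a group. Of 47 measured members, 21 were at least 2-fold higher and 0 at least 2-fold lower, and the median log2 ratio was 0.95 (percentile 100). IFIT2, whose product binds viral RNA, was 50.8-fold higher (45.4 to 57.0), OASL 35.1-fold (27.1 to 46.5) and IFIT3 9.85-fold (9.14 to 10.6). In ODN cells with fewer than 3 interferon UMIs, an alternative chosen after seeing the data, the log2 ratios of these 3 genes were 4.28, 3.05 and 2.40 instead of 5.67, 5.14 and 3.30. The list as a whole moved little there, with 22 of 47 members at least 2-fold higher and a median of 0.92. Of 22 measured cytokine and chemokine genes, 18 were at least 2-fold higher and 2 at least 2-fold lower (median 3.98 at the bound, percentile 100). In ODN cells with fewer than 3 interferon UMIs 10 of 16 were higher and 2 lower (median 2.09), and with 1 UMI added the median was 2.86. CCL4L2, a near-identical copy of CCL4, had 1 control UMI and a ratio of 2001 (359 to 79055), and its reads cannot be separated with certainty from those of CCL4.

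Genes of the NF-kB pathway, the main inflammatory signalling route below Toll-like receptors, had 11 of 18 measured members at least 2-fold higher and 0 lower (median 1.33, percentile 100). The survival gene BCL2A1 was 36.6-fold higher (31.1 to 43.4), the ubiquitin ligase gene BIRC3 5.08-fold and NFKB1 itself 4.89-fold. The log2 ratio of BCL2A1 was 6.37 in the jointly clustered class and 3.80 in ODN cells with fewer than 3 interferon UMIs instead of 5.19. In the latter cells BIRC3 was at 1.55 instead of 2.34 and NFKB1 at 1.54 instead of 2.29. In the maturation and co-stimulation list, 15 of 22 measured members were at least 2-fold higher and 1 at least 2-fold lower (median 1.64 at the bound, percentile 100). Of the 22, 1 had 0 UMIs in 1 of the sums. CD69, an early activation receptor, was 26.4-fold higher (18.2 to 39.97). Its log2 ratio, 4.72 as reported, was 5.53 with the mean of per-cell CPM, 5.45 with cells thinned and 5.47 in the jointly clustered class. CCR7, which guides dendritic cells to lymph nodes, was 23.5-fold higher (18.3 to 30.6), and the T cell co-stimulator TNFSF9 21.4-fold (8.17 to 79.7). The log2 ratio of CCR7 was 2.91 over all cells instead of 4.55, and CCR7 stood at 688 CPM in the unnamed control cluster led by FSCN1, which is outside these sums. In the jointly clustered class 19 of 21 maturation genes were at least 2-fold higher (median 2.54), and without the CX3CR1-led control cluster 17 of 21 (median 2.15). Immediate early and heat shock genes had 22 of 32 members at least 2-fold higher (median 1.57, percentile 100), with the nuclear receptor NR4A3 14.7-fold higher (12.1 to 18.0). HSPA1A was 11.3-fold and its near-identical copy HSPA1B 12.5-fold higher, with the division of UMIs between them uncertain. Without clusters led by stress genes, an alternative chosen after seeing the data, 13 of 27 members of this list were at least 2-fold higher (median 0.92), and the log2 ratios of HSPA1A and HSPA1B were 1.60 and 1.56 instead of 3.50 and 3.65. NR4A3 went the other way, at 5.14 instead of 3.88, but in ODN cells with fewer than 3 interferon UMIs it was at 2.51 (2.21 to 2.83).

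Amino acid transport is the process named in the series title. SLC7A5 (ENSG00000103257, chromosome 16, 87830023 to 87869488) encodes LAT1, which imports large neutral amino acids such as leucine. It stood at 283 CPM in the ODN library and 313 CPM in the control library, a ratio of 0.905 (0.839 to 0.976). Its log2 ratio of -0.14 turned to 0.01 with the size factor and to 0.04 over all cells. SLC3A2 (ENSG00000168003, chromosome 11, 62856102 to 62888875) encodes CD98hc, the heavy chain that carries LAT1 to the cell surface. It stood at 121 and 126 CPM, a ratio of 0.961 (0.854 to 1.08), with a log2 ratio of -0.06 that turned to 0.09 with the size factor. In alternatives chosen after seeing the data it lay in either direction, at 0.27 (0.08 to 0.46) in ODN cells with fewer than 3 interferon UMIs and -0.27 (-0.47 to -0.06) without stress-led clusters.

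Other genes of the amino acid transporter list differed more, in both directions. The cystine and glutamate exchanger gene SLC7A11 was 3.09-fold higher in the ODN library (2.68 to 3.58). SLC43A3, a member of the fixed list that is not an established amino acid transporter, was 2.79-fold higher (2.42 to 3.22). SLC1A3, a glutamate transporter gene with 2 control UMIs, had a ratio of 13.5 (3.52 to 115). The glutamine transporter gene SLC1A5 was 3.01-fold lower (2.57 to 3.53), SLC43A2, which carries branched-chain amino acids, 5.13-fold lower (3.38 to 7.99), and the lysosomal transporter gene PQLC2 3.36-fold lower. SLC15A3 was 2.12-fold lower, SLC38A1 1.90-fold, SLC7A6 1.85-fold, SLC38A7 1.59-fold and SLC38A2 1.52-fold lower, while SLC38A5 was 1.55-fold and SLC38A10 1.51-fold higher. Of 23 measured members, 3 were at least 2-fold higher, SLC43A3 among them, and 4 at least 2-fold lower. The list's median of -0.21 lay at percentile 28.0 of random lists. With ODN cells that held at least 3 interferon UMIs left out, an alternative chosen after seeing the data, the log2 ratio of SLC7A11 was 0.28 rather than 1.63.

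**Figure D1:**
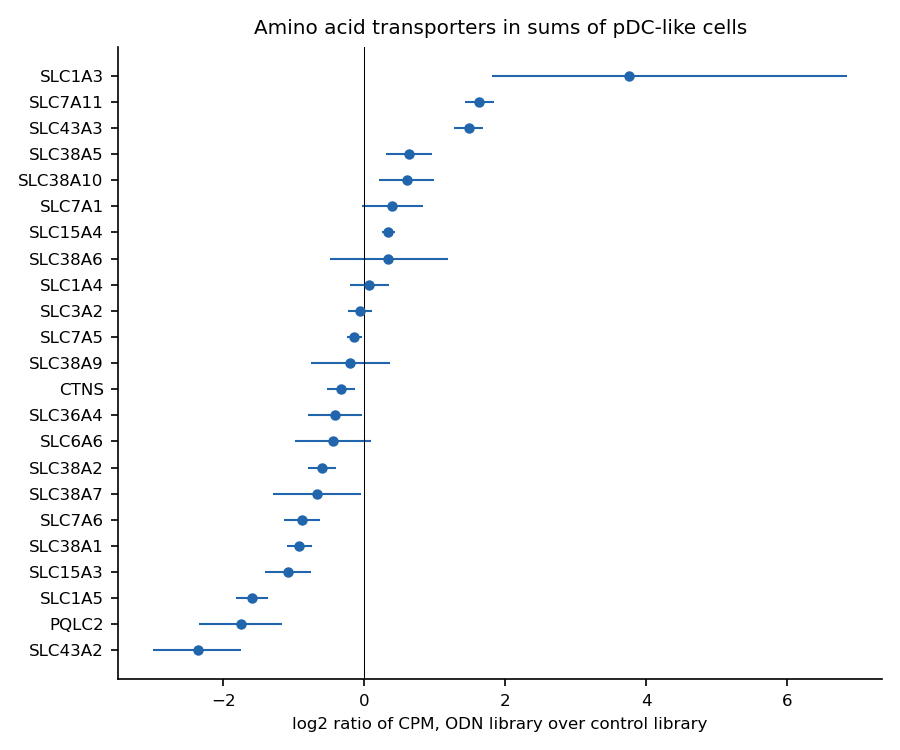
Log2 ratio of CPM (ODN library over control library, horizontal axis) for the 23 measured genes of the amino acid transporter list in sums of pDC-like cells. Points are ratios and bars exact 95% intervals that cover counting error only. SLC7A5 (-0.14) and SLC3A2 (-0.06) lie near 0, and both change sign with the size factor, while SLC7A11 lies at 1.63 and SLC43A2 at -2.36.

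Lists tied to amino acid sensing and translation showed no common direction. For the machinery of mTORC1, the kinase complex that senses amino acids, 1 of 36 measured members was at least 2-fold higher and 3 were at least 2-fold lower. Its median of -0.14 (percentile 54.5) turned to 0.01 with the size factor. AKT1S1 was 2.06-fold higher (1.82 to 2.33), EIF4EBP1, a repressor of cap-dependent translation, 3.38-fold lower (2.66 to 4.32) and the leucine sensor gene SESN2 4.66-fold lower (2.13 to 11.3). Of 16 genes of the ATF4 and amino acid response, 3 were at least 2-fold higher and 2 at least 2-fold lower (median 0.18, percentile 96.1), and this median was -0.49 with a minimum of 10 UMIs. ATF3 was 9.11-fold higher (7.89 to 10.6) and PPP1R15A, which restarts translation after stress, 6.83-fold (6.33 to 7.39). The log2 ratio of ATF3 was 5.56 without stress-led clusters instead of 3.19, and that of PPP1R15A was 1.35 in ODN cells with fewer than 3 interferon UMIs instead of 2.77. The cytosolic aminoacyl-tRNA synthetases, which load amino acids onto transfer RNA, lay lower, with a median of -0.50 over 20 members (percentile 0.37) and 1 member at least 2-fold higher and 1 lower. HARS was 2.78-fold higher, WARS 1.94-fold higher and NARS 1.81-fold lower. In ODN cells with fewer than 3 interferon UMIs the log2 ratios of HARS and WARS were 0.06 and 0.14 instead of 1.47 and 0.96. Of 27 nucleolar and ribosome biogenesis genes, 0 were at least 2-fold higher and 1 at least 2-fold lower (median -0.24, percentile 19.0). Translation factors had 0 of 33 members at that size (median -0.19, percentile 13.9).

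Genes of cholesterol and fatty acid synthesis were lower as a group. Of 30 measured members, 13 were at least 2-fold lower and 2 at least 2-fold higher, with a median of -0.85 (percentile 0.00). The mevalonate pathway gene MVD was 3.81-fold lower (2.96 to 4.94) and the fatty acid desaturase gene FADS1 3.58-fold lower (2.60 to 4.99). The glycolysis list had a median of -0.46 over 20 members (percentile 0.52), with 4 at least 2-fold higher and 2 at least 2-fold lower. The 3 members that the naming rule picked were all higher, against the direction of the list's median. The glycolytic activator gene PFKFB3 was 3.28-fold higher (2.21 to 5.03) and the oxygen-response regulator HIF1A 3.27-fold higher (2.82 to 3.79). The hexokinase gene HK2 was 5.79-fold higher (2.08 to 22.4), on 36 ODN and 4 control UMIs. Nuclear-encoded oxidative phosphorylation genes had 0 of 40 members at least 2-fold higher or lower (median -0.21, percentile 8.08). The 13 mitochondrially encoded genes had a median of -0.39 (percentile 1.31), with MT-ND3 2.14-fold lower and no member at least 2-fold higher.

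Genes of pDC identity were lower on balance, with 6 of 33 measured members at least 2-fold lower, 0 at least 2-fold higher and a median of -0.42 (percentile 0.00). LRRC26 was 11.0-fold lower (5.98 to 22.1), SERPINF1 2.86-fold (2.67 to 3.07) and SMPD3 2.62-fold. The markers used to call clusters pDC-like include members of this list, such as SERPINF1, so these genes also helped choose the cells compared. Over all cells, which were not chosen on these markers, 6 of 33 members were at least 2-fold lower and the median was -0.36. All cells also take in the unnamed and cycling classes. The median was -0.58 in the jointly clustered class and -0.28 in ODN cells with fewer than 3 interferon UMIs. Of 13 pDC surface receptors, 6 were at least 2-fold lower and 1 at least 2-fold higher (median -0.45, percentile 1.64). CLEC4A, an inhibitory lectin receptor gene, was 6.49-fold lower (4.27 to 10.2), CD300A 3.31-fold lower, and the inhibitory receptor gene LILRB2 11.2-fold higher (5.73 to 24.9). The log2 ratio of CLEC4A, -2.70 as reported, was -1.37 without the CX3CR1-led control cluster, -1.18 over all cells and -0.84 in the jointly clustered class, where its interval (-1.74 to 0.06) holds 0. In ODN cells with fewer than 3 interferon UMIs LILRB2 was at 2.43 (1.36 to 3.66) instead of 3.48 and CD300A at -1.08 instead of -1.73. CD300A was at -2.60 without stress-led clusters and -2.32 in the jointly clustered class. The TLR7/9 and IRF7 pathway had 3 of 26 members at least 2-fold higher and 2 at least 2-fold lower (median 0.04, percentile 83.4), and the median turned to -0.06 with the mean of per-cell CPM. TLR9 itself is not among these members, since it had too few UMIs to be measured, with 0 in the ODN pDC-like cells. Whether the gene model used for counting covers the end of the TLR9 transcript that was sequenced was not checked, so this 0 says nothing about its expression. CXorf21, an adaptor of endosomal Toll-like receptors, was 2.79-fold higher (2.51 to 3.11), and BLNK and SYK, which signal below pDC surface receptors, were 2.94-fold and 2.83-fold lower.

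Of 27 genes of the unfolded protein response and secretion, 2 were at least 2-fold higher and 0 lower (median 0.03, percentile 77.7; -0.01 with the strict cell filter), and XBP1, a transcription factor of secretory cells, was 2.02-fold higher. Apoptosis genes had 4 of 22 members at least 2-fold higher and 0 lower (median 0.46, percentile 100). Without the CX3CR1-led control cluster 5 of 21 were higher and 3 lower (median 0.63), and in the jointly clustered class 7 higher and 2 lower (median 0.64). The pro-apoptotic genes BCL2L11 and PMAIP1 were 8.37-fold (6.04 to 11.9) and 8.16-fold (7.39 to 9.02) higher, and the anti-apoptotic BCL2 4.38-fold (2.97 to 6.66) higher. The log2 ratio of PMAIP1, 3.03 as reported, was 4.00 without stress-led clusters, and its interval was 1.84 to 2.16 in ODN cells with fewer than 3 interferon UMIs. MHC class I presentation genes had 0 of 18 members at that size (median 0.15, percentile 93.2), with HLA-E 1.75-fold and TAP1 1.48-fold higher. MHC class II genes had a median of -0.41 over 14 members (percentile 0.89), with 1 at least 2-fold lower and 0 higher. This shift rests largely on the CX3CR1-led control cluster. Without it the median was -0.17, and in the jointly clustered class -0.18, close to the median over all measured genes. IFI30, a lysosomal thiol reductase gene of antigen processing, was 3.35-fold lower, and HLA-DPB1 1.79-fold lower. In the jointly clustered class the log2 ratio of IFI30 was -0.18 instead of -1.75. HLA genes have close copies, so their values are uncertain. Cytosolic ribosomal protein genes had a median of -0.30 over 79 members (percentile 0.00), with 2 at least 2-fold lower. Of these, RPS10 was 2.69-fold and RPL36A 2.10-fold lower, both uncertain because of processed copies in the genome. Of 21 cell cycle genes, 8 were at least 2-fold higher (median 0.42, percentile 99.9), although cycling cells form a class outside these sums. This depends on the choice of cells and genes. Over all cells 0 of 24 were at least 2-fold higher (median 0.27), with a minimum of 100 UMIs 1 of 12 (median -0.0625), and with cells thinned to the same depth 0 of 11, with 3 lower (median -0.29). MKI67 was 10.6-fold higher (4.71 to 29.6), with UMIs in 6.06% of ODN cells and 0.456% of control cells. Over all cells its log2 ratio was 0.93 instead of 3.41.

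**Figure D2:**
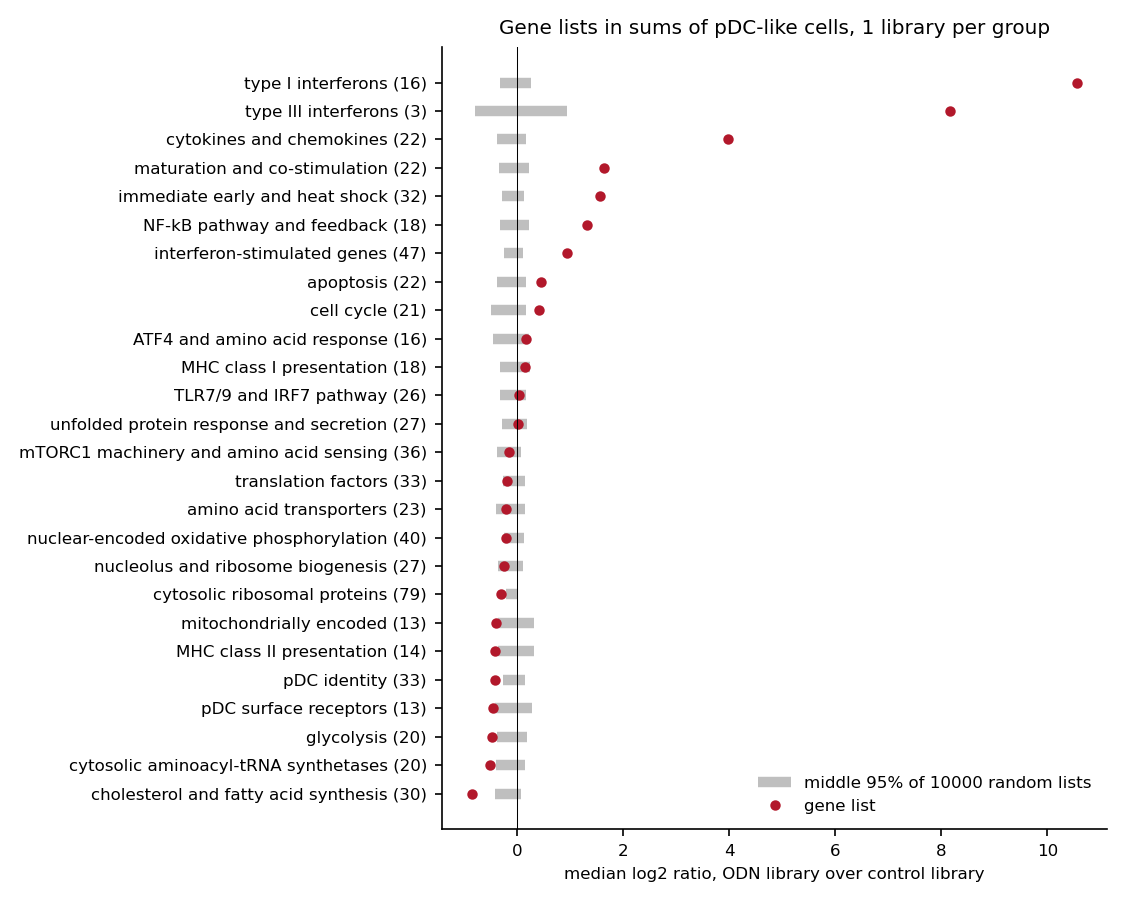
Median log2 ratio (ODN library over control library, horizontal axis) of the 26 gene lists in sums of pDC-like cells, with measured members in parentheses. Points are list medians, with genes at 0 in the control at their bound, and grey bars span the middle 95% of 10000 random lists. Type I interferons lie at 10.55 and cholesterol and fatty acid synthesis at -0.85, and the mTORC1 list changes sign with the size factor.

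The 15 genes picked as lowest in the ODN library were LRRC25, SLA, TBC1D2B, LYZ, RXRA, LRRC26, PHLDA3, FGL2, NOTCH4, RGS18, CBFA2T3, S100B, DAPK2, SNAI3 and PROC. LRRC25 had the largest ratio, at 29.5-fold lower (11.1 to 111). TBC1D2B was 11.0-fold lower (7.27 to 17.3), the nuclear receptor gene RXRA 9.26-fold (6.86 to 12.7), and CBFA2T3, a transcriptional corepressor gene, 6.59-fold (5.33 to 8.20). The lysozyme gene LYZ was 8.66-fold lower (7.25 to 10.4), FGL2 9.42-fold and S100B 12.4-fold. S100B UMIs lay in 0.456% of the control cells and 0.818% of the ODN cells, so this ratio rests on very few cells. These 3 genes rest largely on control cluster 6. Without it, a choice made after seeing the data, their log2 ratios were -0.92, -0.31 and -0.05. For LYZ the direction also turned, with a log2 ratio of 4.31 (2.92 to 6.20) in the jointly clustered class and 0.0046 over all cells, so it is not read as lower in pDC. SLA and PHLDA3 rest on this cluster in part. Without it SLA fell from 59 to 13 control UMIs and its log2 ratio was -2.42 (-4.27 to -0.85) instead of -4.20, and PHLDA3 fell from 196 to 89 UMIs, at -2.31 instead of -3.04.

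The next comparison asks what share of pDC-like cells held interferon RNA. After thinning each cell to 4000 UMIs, 309 of 575 ODN cells held at least 1 type I or III interferon UMI (53.7%, 49.6 to 57.9%), against 1 of 374 control cells (0.267%, 0.007 to 1.48%). Thinning left out 36 shallower ODN cells and 65 control cells, and the median depths were 7234 and 7809 UMIs. Without thinning the shares were 62.4% and 1.37%. No other blood lineage was found in the ODN library to give a background. The small unnamed ODN clusters, led by FSCN1 and by LYZ, held interferon UMIs in 7 of 14 and 10 of 16 barcodes without thinning, 2 or more in 3 and 4 of them, and after thinning at least 1 in 4 and 5. In its barcodes nearly free of MALAT1 and mitochondrial UMIs, 5 of the 16 deep enough held at least 1 interferon UMI (31.3%, 11.0 to 58.7%), and without thinning 9 of 51 did (17.6%, median depth 3466 UMIs). None of these 51 held 2 or more, which allows a share of up to 5.88% at a floor of 3 counts (exact upper limit 6.98%). At 3 or more UMIs the thinned share of ODN pDC-like cells was 28.9% (25.2 to 32.8%), and at 10 or more it was 25.0% (21.6 to 28.8%). The unthinned ODN library held 165236 interferon UMIs, 2.35% of its total, and the control library held 7.

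Interferon UMIs were concentrated in a small part of the ODN pDC-like cells. The top 1% of cells held 21.4% of them, the top 5% held 54.6% and the top 10% held 78.8%. For 5 genes of like total, the top 10% of cells held between 22.7 and 31.2%. IFNL1 was the most concentrated of the genes followed, with 94.9% in the top 10% of cells, next to 79.7% for CCL3, 45.4% for IFIT2, 43.0% for SLC7A5 and 27.1% for the antiviral modifier gene ISG15. These figures describe 1 library at its own depths.

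**Figure D3:**
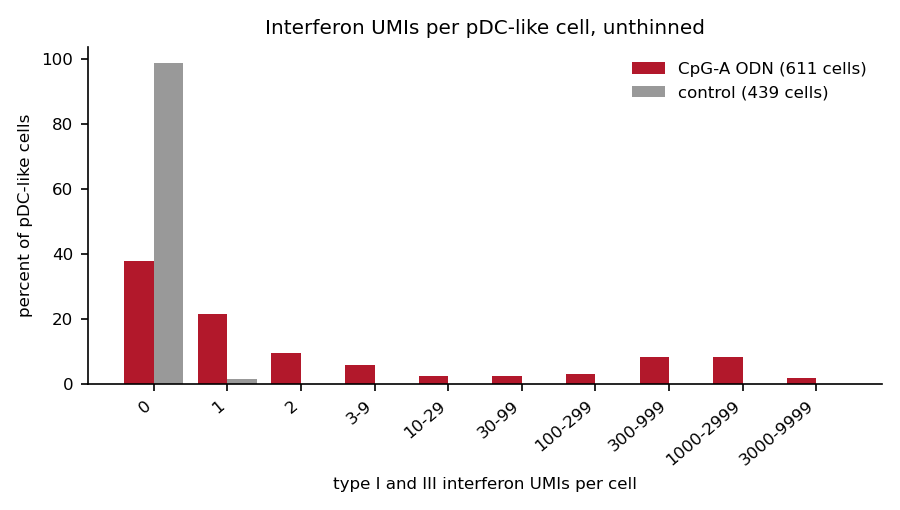
Percent of pDC-like cells (vertical axis) by the number of type I and III interferon UMIs in the cell (horizontal axis, bins of unequal width), unthinned, for the ODN library (611 cells) and the control library (439 cells). In the ODN library 37.6% of cells held 0 and 8.35% held 1000 to 2999, while 98.6% of control cells held 0.

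The last comparison lies within the ODN library and sets the 193 pDC-like cells with at least 3 interferon UMIs against the other 418, with interferon genes left out of the sums. Further cytokine and mediator genes were higher in the interferon-holding cells. IL12A, which encodes a subunit of interleukin-12, had 195 UMIs there and 0 in the other cells. PTGS2, which makes prostaglandin precursors, was 111-fold higher (53.8 to 278), and the cytokine gene IL27 63.8-fold (29.03 to 175). DUSP1, a phosphatase gene that ends kinase signalling, was 20.5-fold lower (8.55 to 64.4), the chemokine gene CCL1 15.6-fold lower (5.82 to 58.7) and ID3 7.78-fold lower (5.04 to 12.6). With the split at 1 UMI the log2 ratio of DUSP1 was -1.54 (-2.08 to -1.01) instead of -4.36. The split marks a range of cells and no cell type, and 35 cells held 3 to 9 interferon UMIs, close to it. Median depths were 10469 and 6740.5 UMIs, and cells are not replicates.

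The same rule of size also picked TAL1, SH2D4A, TTN, FST, AFAP1, NR5A2, GCSAML, FAM198B, GPR34, MYOM1, PLEKHA4 and the noncoding gene RP11-532F6.3 as highest in the interferon-holding cells. Of these, MYOM1, which encodes a sarcomere protein, had the most UMIs and was 28.1-fold higher (23.0 to 34.7), and GPR34, a lysophospholipid receptor gene, was 32.4-fold higher (23.0 to 47.1). Picked as lowest were also HSPA1B, FSTL3, ZNF331, MT1X, APOBEC3A, HIST1H2AC, FILIP1L, RGS2, DNAJB1, DDIT4, EGLN3 and DUSP10. The heat shock gene DNAJB1 was 3.37-fold lower (2.84 to 4.00). Among the 20 measured members of the fixed cytokine and chemokine list, which leaves out CCL1, 14 were at least 2-fold higher and 0 lower, with a median log2 ratio of 1.99 (percentile 100). CCL3 was 5.78-fold higher (5.47 to 6.12), CCL4 2.84-fold and TNF 2.21-fold. The interferon-stimulated list showed no such shift, with a median of 0.07 over 47 members (percentile 87.8). IFIT2 was 4.61-fold higher (4.47 to 4.76), while ISG15 was 1.20-fold lower (1.17 to 1.23). NF-kB genes had a median of 0.68 and maturation genes 0.46, with CD40, a co-stimulatory receptor gene, 2.02-fold higher. Immediate early and heat shock genes had a median of -0.31 (percentile 0.05) and oxidative phosphorylation genes -0.28 (percentile 0.02). Of the genes picked as lowest, DNAJB1, ZNF331 and RGS2 also led the stress-led ODN cluster 2, and HIST1H2AC led cluster 1. How the cells of these clusters fall on the sides of the split was not counted, and no split without them was made. Lower stress genes in interferon-holding cells and stress-led clusters among the other cells therefore cannot be told apart. Of 19 measured cell cycle genes, 8 were at least 2-fold higher and 1 at least 2-fold lower (median 0.55, percentile 99.98). This list was not followed under the alternatives of the split. Between the libraries its median turned to -0.29 with cells thinned to the same depth.

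SLC7A5 was at 299 CPM in the interferon-holding cells and 284 CPM in the others, a ratio of 1.05 (0.953 to 1.16), which turned to a log2 ratio of -0.03 with the split at 10 UMIs. SLC3A2 was 1.62-fold lower (1.38 to 1.90) and SLC7A11 4.46-fold higher (3.85 to 5.19). SLC3A2 stood at 368 and 269 CPM in the stress-led ODN clusters 1 and 2, and at 83.3 CPM in the interferon-led cluster 3. The other pDC-like ODN clusters, at 81.1 to 105 CPM, lay close to cluster 3. Lower SLC3A2 in interferon-holding cells and stress-led clusters among the other cells therefore cannot be told apart either. The amino acid transporter list had a median of 0.07 over 23 members (percentile 75.1), which turned to -0.13 with cells thinned to the same depth. Median UMIs per cell after thinning were 1 and 0 for SLC7A11, 29 and 3 for IFIT2, and 16 and 21 for ISG15. For IL12A, PTGS2, IL27, GPR34, MYOM1, DUSP1, CCL1, ID3 and DNAJB1 both medians were 0. The large ratios of these genes therefore rest on part of the cells. TNF, CD40, ISG15 and IRF7 fall outside the naming rule and were chosen after their values could be seen. IRF7, the transcription factor that drives alpha interferon genes, was 1.25-fold lower (1.20 to 1.30) in the interferon-holding cells.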

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

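Tests on the rankings of leading genes, the jointly clustered class, the CX3CR1-led cluster, the stress-led clusters and the ODN cells with fewer than 3 interferon UMIs were chosen only after the results were seen. No paired analysis was possible because the result comes from no test and each group has 1 library. The filter at 200 genes removed 0 barcodes, so leaving it out tests nothing. Where a value below differs from the reported value, the cause was not tested. Apart from SLC7A5, SLC3A2, the interferon-stimulated, cytokine and amino acid transporter medians, the shares and the overlaps of picked genes, the alternatives fixed in advance left 1190 within the counting interval or the redraws of a list and moved 178, and the added ones left 562 and moved 213. Of the values whose interval or redraws left out 0, a further 5 and 2 turned in sign. Values near 0 that changed sign within their interval or redraws, such as the mTORC1 median, count as left. Leaving out the cell filter or changing the minimum of UMIs cannot change the ratio of a gene, yet such ratios count among the 1190. Of the added alternatives, the ranking against the rest and the sums without the CX3CR1-led control cluster hold the same cells and are counted separately. These numbers therefore do not measure how stable the results are. Of the 15 highest genes, 14 or 15 were kept under each alternative except the ODN cells with fewer than 3 interferon UMIs.

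With the size factor the log2 ratio of SLC7A5 was 0.0054, and the medians were 1.10 for interferon-stimulated genes and -0.0557 for amino acid transporters. With the mean of per-cell CPM the interferon-stimulated median was 0.98, and 9 of the 15 lowest genes were among the reported 15. Over all cells this number was also 9, SLC7A5 was at 0.0414, LYZ at 0.0046, CCL3 at 8.16 and CCR7 at 2.91. At a minimum of 10 UMIs the cytokine and chemokine median was 3.41 and the ATF4 median -0.49. At a minimum of 100 UMIs they were 4.86 for cytokines and chemokines and -0.0625 for cell cycle, with 8 of the 15 lowest genes shared. With the strict filter the cytokine median was 4.25. With cells thinned the medians were 8.91 for type I and 6.56 for type III interferons, IFNB1 was at 10.87, and the cytokine median was 3.50, next to -0.42 for amino acid transporters and -0.29 for cell cycle, with 8 lowest genes shared. With 1 UMI added, medians were 12.09 and 9.75 for type I and III interferons, 2.86 for cytokines, -0.38 for amino acid transporters and -0.48 for ATF4.

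Where leading genes were ranked against the rest, and equally without the CX3CR1-led control cluster, 9 lowest genes were shared and the cytokine median was 4.35. Ranked against low-marker clusters it was 4.25. In the jointly clustered class it was 4.39, LYZ was at 4.31, AKT1S1 at 1.93 and PHLDA3 at -1.57, and 9 lowest genes were shared. Without stress-led clusters it was 4.32, SLC3A2 was at -0.27, PMAIP1 at 4.00, SLC7A11 at 2.22 and SLC43A2 at -3.00. In ODN cells with fewer than 3 interferon UMIs it was 2.09, SLC3A2 was at 0.27, HIF1A at 1.09, LILRB2 at 2.43, NR4A3 at 2.51, cell cycle at -0.20, and 2 of the 15 highest genes were shared, since these cells were picked for holding little interferon RNA.

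The ODN pDC-like share was 77.8% at resolution 2.0. The control share was 56.0% at resolution 0.5, 71.9% at 2.0, 72.4% with the strict filter, 51.0% ranked against the rest and 71.6% against low-marker clusters. The share of ODN cells with interferon was 62.4% unthinned, 33.4% thinned to 1000 UMIs, 33.6% at 2 or more UMIs and 28.9% at 3 or more. The control share was 0.0% at 1000 UMIs (0 of 439 cells, which allows up to 0.683% at a floor of 3 counts, exact upper limit 0.837%) and 0.0% at 2 and at 3 or more UMIs. The top 10% of cells held 81.4% of interferon UMIs when thinned. Within the ODN library the cytokine median was 1.61, PTGS2 at 5.75, HSPA1B at -1.82 and DUSP1 at -1.54 split at 1 UMI, and the transporter median was -0.13 when thinned.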

Other observations

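Of the tests in this part, only the part of IFNB1 among interferon UMIs was fixed before its result was seen, and the others were chosen after. SLC3A2 and SLC7A5 differed in how they spread over the pDC-like clusters. SLC3A2 was highest in the clusters led by stress or heat shock genes. In the ODN library it stood at 368 CPM (315 to 427, counting error only) in cluster 1 and 269 CPM (215 to 333) in cluster 2, against 81.1 to 105 CPM in the other pDC-like clusters. In the control library it stood at 244 CPM (204 to 291) in cluster 3, against 92.0 to 122 CPM in the others. SLC7A5 followed this less closely. In the ODN library it stood at 398 CPM (343 to 459) in cluster 1 and 339 CPM (278 to 409) in cluster 2, but also at 347 CPM (309 to 388) in cluster 6, and lowest, at 151 CPM (125 to 182), in cluster 4. In the control library it ranged from 266 CPM in cluster 6 to 377 CPM in cluster 5, with cluster 3 at 309 CPM. Barcodes nearly free of both MALAT1 and mitochondrial UMIs held little SLC7A5, at 25.5 CPM in the ODN library and 37.5 CPM in the control library, but SLC3A2 there stood at 132 and 178 CPM. Such barcodes made up 6.96% of the ODN library and 16.3% of the control library. These do not include a ribosomal-led control cluster of 17 barcodes, which was nearly free of MALAT1 but had a median of 1.12% mitochondrial UMIs.

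In the ODN library, 188 pDC-like cells held only 1 or 2 interferon UMIs, while 129 held at least 100. Free RNA shed by the rich cells is a candidate source of the small numbers. IFNB1 took 16.3% (11.9 to 21.6%) of the 245 interferon UMIs in the poor cells and 16.3% in the rich cells, as free RNA would give, although low expression of the same genes would give the same part. The rate in cells with fewer than 3 was 0.813 interferon UMIs per 10000 UMIs (0.714 to 0.921), against 0.458 (0.210 to 0.870, 9 UMIs) in the barcodes nearly free of MALAT1 and mitochondrial UMIs. These intervals overlap, so low expression by the cells themselves and background cannot be told apart with 9 UMIs.

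Both libraries held barcodes nearly free of MALAT1 and mitochondrial UMIs, 51 and 120 of them. Droplets holding only free RNA would carry the ODN library's abundant RNA, but IFIT2 in the 51 ODN barcodes stood at 0.0249 of its level over the library (0.0147 to 0.0393), which argues against that source. Over the 20 response genes most abundant in the ODN library this part had a median of 0.104, from 0.0035 for CCL3 to 1.36 for LTB, with 13 below 0.5. Interferon UMIs stood at 0.458 per 10000 UMIs against 235 over the library. The response genes above 0.5 were LTB, IFI6 at 1.25, IFI27 at 1.13, MX1 at 0.84, LY6E at 0.76, ISG15 at 0.73 and ISG20 at 0.51. Not all abundant response RNA was therefore scarce there. ISG15 also stood at 3100 CPM in the control barcodes. Over 47 response genes the median log2 ratio of ODN to control was 0.0151 (-0.10 to 0.20) in these barcodes and 0.84 in pDC-like cells. Remnants whose RNA largely predates the treatment would give such a value. They would also hold pDC genes alike in both libraries, but over 24 genes of pDC identity the median log2 ratio was -0.69 (-0.78 to -0.47) in these barcodes. GZMB stood at 1456 CPM (1292 to 1635) in the ODN barcodes and 3928 CPM (3737 to 4127) in the control barcodes, and CLEC4C at 153 CPM (103 to 218) and 323 CPM (269 to 383). Such remnants and a difference between the cultures or donors therefore cannot be told apart with 1 library per treatment. No biological explanation was tested.

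The genes picked as lowest in the ODN library may partly reflect which clusters entered the class, since control cluster 6 was in it and an ODN cluster led by LYZ was not. Without control cluster 6 the log2 ratio of LYZ was -0.92 (-1.27 to -0.57) instead of -3.11. For FGL2 and S100B the median was -0.18 instead of -3.44, so their lower level rests on this cluster, with intervals of -1.60 to 1.06 and -2.27 to 2.58 without it. For the other 12 genes the median was -3.10 (range -4.66 to -2.31) instead of -3.33. These 12 are what was left once the genes that moved most had been set apart on the same values. That their median stayed low was therefore fixed by this choice and tests nothing. By size alone, each of them was still lower in the ODN library without the cluster. The size factor shifts every gene alike, and it moved the median over all measured genes from -0.15 to 0.00. The median of these 12 with FGL2 and S100B was therefore bound to move by as little, to -3.18 instead of -3.33. This is no separate test of scaling in a library rich in interferon RNA. A scaling shift of that size is small next to their ratios. The response to CpG-A ODN and a difference between the cultures or donors stay open for these 12 genes and were not tested.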
